A study of Mus musculus with 70 samples.

How the data were processed

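RNA was sequenced from 70 libraries of sorted splenic dendritic cells and monocytes, taken 5 h after an intraperitoneal injection of PBS. Per the labels, RNA was extracted with a kit for small samples, amplified with a SMART-seq v4 low-input kit and sequenced on a NextSeq instrument. The 23 Rag1-/- libraries all belong to sequencing run 1 and the 47 Rag-sufficient libraries (NOD and B6g7) to run 2. Rag-sufficient libraries came from 537 to 5000 sorted cells and Rag1-/- libraries from 6575 to 14529, so genotype, run, sort date and cell number cannot be told apart between the sets. The RNA integrity number ranged from 3.9 to 10 in the Rag-sufficient set and from 8.1 to 9.5 in the Rag1-/- set. It was under 7 in cDC2 B6g7 5 (6.8) and cDC2 B6g7 6 (3.9).

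The authors deposited a table of 35070 RefSeq transcripts whose name says CPM, but whose values are estimated counts: its column totals are whole numbers between 12.8 M and 20.6 M, and 35.7% of its entries above 0 are fractional. These expected counts come from RSEM per the labels, with no version given. The authors also deposited post-processed values on a log2 scale, read here as a score without a unit, for 24628 transcripts of the Rag-sufficient set and 27044 of the Rag1-/- set. In the Rag1-/- score table all libraries have nearly the same distribution. The deposited comparison tables hold, per the file headers, a log2 fold change and an adjusted p-value for each of 21868 and 27044 transcripts, which the authors made with limma. The aligner, genome build and annotation release are not given in the sources used here, so no coordinates are printed, and chromosomes were read from the deposited transcript identifiers.

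Before the data were examined, the groups, tests, gene lists, the rule for named genes and most alternatives were fixed. The design assumed CPM values, tested with limma on log2 values after median-of-ratios scaling. Because the values are counts, the main test became the edgeR quasi-likelihood test, and limma on log2 CPM was kept as an alternative. Expected counts were summed over the transcripts of each gene and rounded, which gave 24429 genes, 19106 of them with any count. Gene names came from RefSeq by transcript accession for 34706 transcripts and from the authors' tables for 266, and 98 had no name. Genes with a CPM of at least 1 in at least 3 libraries of a fit were tested: 13413 in the Rag-sufficient set, 13137 in the Rag1-/- set and 13837 in all libraries. Reads of near-identical genes, such as MHC paralogs, may be assigned to the wrong member. Single genes of this kind, MHC genes among them, are less certain than others.

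Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. TMM factors ranged from 0.587 to 1.345 (edgeR calcNormFactors). The Rag-sufficient fit held 8 strata of cell type and sort date and 5 strain effects (34 residual degrees of freedom), with a common dispersion of 0.0490. The Rag1-/- fit held 1 mean per cell type and strain (15 residual degrees of freedom), with a common dispersion of 0.196. These are biological coefficients of variation of 22.1% and 44.2%. Dispersions and quasi-likelihood fits were robust. A further fit over all libraries tested whether the strain effect differed between the sets. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method per contrast with a threshold of 0.05. Log2 changes are NOD minus B6g7, or NOD Rag1-/- minus B6 Rag1-/-, with the model's standard error (SE), and levels are TMM-scaled CPM with the standard deviation (SD) over libraries.

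The 11 measured gene groups were type I interferon-stimulated genes, interferon-gamma-associated genes, interferon production and sensing, NF-kB and inflammatory genes, MHC class I antigen presentation, MHC class II antigen presentation, costimulation and dendritic cell maturation, cholesterol synthesis, cell cycle, immediate early and heat shock genes, and diabetes-locus candidate genes. A list of mitochondrially encoded genes had no member in the table. The 12 marker lists covered cDC1, cDC2, pDC, monocytes and macrophages, red pulp macrophages, B cells, T cells, NK cells, neutrophils, erythroid cells, platelets and plasma cells. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the gene groups and, separately, over the marker lists of each contrast. Fry was run beside it. It tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes, and no call rests on it. A list's score is the mean log2 CPM of its members (prior count 2) per library, compared between groups with an exact two-sided permutation test.

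Named genes were, per contrast, the 5 largest rises and 5 largest falls among genes past the threshold with at least 10 CPM in the higher group and no overlap between the groups. Rag1 and the genes shared by all 5 Rag-sufficient contrasts were left out of this ranking, so the largest changes given below exclude them. The rule added up to 4 members per gene group, 8 interferon-response genes whatever their result, the 10 most significant genes shared by all contrasts, and Rag1 and Rag2. Some of the genes so named are not reported here. Markers named from the marker lists were chosen after their values were seen. Levels in CPM given with a contrast use the scaling of its set. Those in the comparison of the sets and among the other observations use the scaling over all libraries and differ slightly. Genes without an established symbol were counted and not named. Where every library of a group was at 0, the fold is a lower bound against 3 counts over the group. Intervals and floors cover counting error only, since amplified reads are not independent molecules.

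The labels do not say whether the libraries of a group come from separate animals. No pair of libraries within a group was a duplicate (smallest chi-square per degree of freedom 9.30 between replicates). Replicate numbers pair the strains by sort date only in Rag1-/- cDC1. Checks on simulated data, with 100 genes changed at each fold in each contrast, recovered 68% to 79% of 2-fold and 89% to 96% of 4-fold changes in the Rag-sufficient set. In the Rag1-/- set they recovered 5% to 13% and 44% to 67%. The changed genes were not drawn from those of low counts, and the dispersions were those of the real fits. False calls were 2.30% to 7.65% of all calls in the Rag-sufficient set and 2% to 5.88% in the Rag1-/- set, the highest in pDC of each.

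Alternatives fixed in advance were no sort date term, each sort date alone, an additive sort date for Rag1-/-, a fit per cell type, no filter, no scaling, a replicate block, limma with pseudocounts of 0.25 and 4 CPM, the authors' post-processed values, leaving out libraries of low RNA integrity, and leaving out each library in turn. Added after seeing the data were limma with a pseudocount of 1 CPM, DESeq2, DESeq2 size factors in edgeR, transcripts in place of genes, the estimated correlation, leaving out the NOD libraries with the highest B cell marker scores, leaving out single libraries in the comparison of the strain effects, and no scaling for the score between genotypes. Random splits and the leave-one-out runs of the comparison of strain effects kept the dispersions and TMM factors of the fit to the real groups. No library and no sample label was left out of the comparisons.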

Results

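The series measured gene expression in splenic conventional dendritic cells of type 1 (cDC1) and type 2 (cDC2), monocyte-derived dendritic cells (moDC), plasmacytoid dendritic cells (pDC) and monocytes of mice aged 8-10 weeks. NOD mice, which develop autoimmune diabetes, were compared with B6g7, C57BL/6 mice that carry the MHC class II haplotype of NOD. The Rag-sufficient set held 6 NOD and 6 B6g7 libraries of cDC1, 6 and 6 of cDC2, 5 and 6 of moDC, 3 and 3 of pDC and 3 and 3 of monocytes. The Rag1-/- set held 3 NOD and 3 B6 libraries each of cDC1, cDC2 and pDC, and 3 NOD and 2 B6 libraries of moDC. Its controls are named B6 Rag1-/-, not B6g7 Rag1-/-. Library totals were 12.8 to 19.7 M expected counts (median 15.9) in the Rag-sufficient set and 14.7 to 20.6 M (median 17.8) in the Rag1-/- set. The 10 most abundant genes took 8.80% to 22.4% of the counts of a Rag-sufficient library and 6.40% to 16.7% of those of a Rag1-/- library. Rag-sufficient cDC1, cDC2 and moDC were sorted on 10.26.2015 and 01.05.2016 with both strains on each date, pDC on 10.16.2015 and monocytes on 01.05.2016.

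Rag1, a recombinase needed to assemble antigen receptors, was counted in all 23 libraries labelled Rag1-/-, with 2 to 44 counts each. Its mean level in NOD Rag1-/- was 0.614 ± 0.437 CPM (SD, n = 3) in cDC1, 0.881 ± 0.479 in cDC2, 0.596 ± 0.320 in moDC and 1.40 ± 1.26 in pDC. In B6 Rag1-/- it was 0.296 ± 0.212 CPM in cDC1, 0.839 ± 0.196 in cDC2, 1.12 ± 1.04 in moDC (n = 2) and 1.86 ± 0.389 in pDC. Of the 41 Rag-sufficient libraries other than pDC, 1 moDC B6g7 library had a count, and it had 1. The 3 pDC B6g7 libraries held 3 to 6 counts (0.336 ± 0.1001 CPM) and pDC NOD 0 to 3 (0.0716 ± 0.124 CPM). For the groups without a count, 3 counts over the group allow up to 0.0299 to 0.0567 CPM. Rag2, its partner, was counted in 1 of the 23 Rag1-/- libraries, in 3 of the 6 Rag-sufficient pDC libraries and in none of the other 41. The counts cover the whole transcript and do not check which part of it was deleted.

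The comparison of NOD with B6g7 addresses whether the type I interferon response differs between the strains, as the series title states, and which other genes differ. Type I interferon-stimulated genes, a list of 55 antiviral effectors, sensors and signalling genes, were lower in NOD in every cell type, with median log2 changes of -0.55 in cDC1, -0.83 in cDC2, -0.60 in moDC, -0.43 in pDC and -0.74 in monocytes. Of the 55 genes, 31 fell in cDC1, 46 in cDC2, 41 in moDC, 16 in pDC and 36 in monocytes, while 1 rose in cDC1, 3 in pDC and 1 in monocytes. Adjusted over the list alone, 44, 50, 42, 22 and 41 fell. The list passed camera's test in each (adjusted p 5.5e-15, 4.2e-27, 2.7e-12, 7.7e-06 and 2.1e-16). With an estimated correlation the call held in cDC2 (adjusted p = 0.0032) and monocytes (adjusted p = 0.041) and was lost in cDC1 (adjusted p = 0.059), moDC (adjusted p = 0.094) and pDC (adjusted p = 0.14). Over all contrasts 37 of 99 gene group tests passed camera's test. With an estimated correlation 7 did: type I genes in cDC2 and monocytes, and in pDC the interferon-gamma-associated, NF-kB, MHC class II, costimulation and diabetes-locus lists. Of the marker lists, only the cDC1 markers in moDC passed with it.

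**Figure D1:**
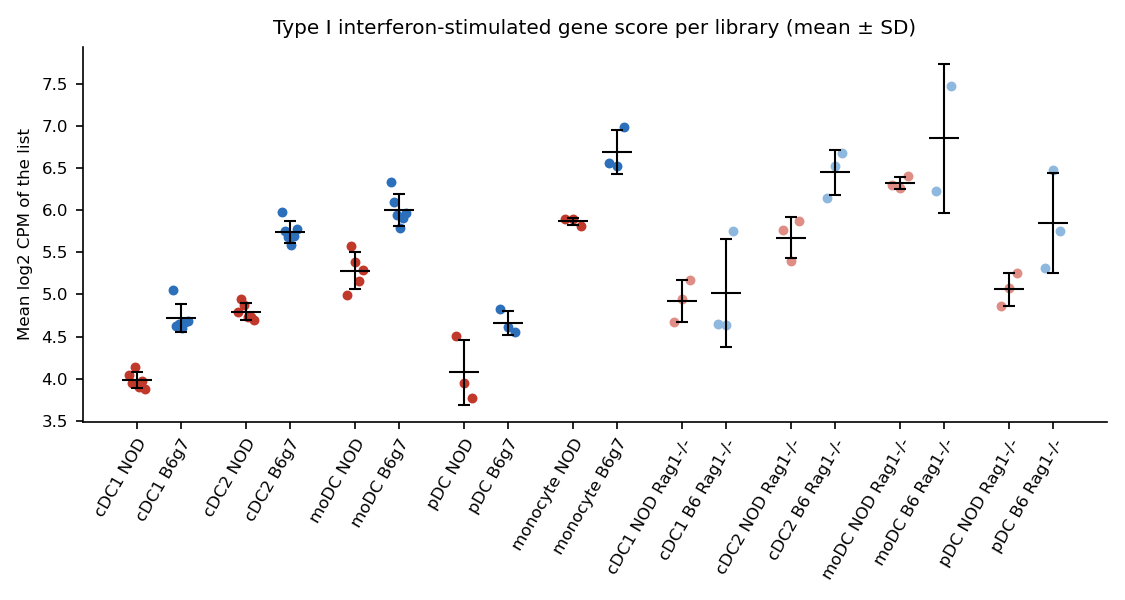
Mean log2 CPM of the 55 type I interferon-stimulated genes (vertical axis) in each library (points) by cell type, strain and genotype (horizontal axis), with lines for the group mean ± SD. In the Rag-sufficient groups all NOD libraries lay below all B6g7 libraries of their cell type, for example 4.80 ± 0.0953 against 5.75 ± 0.131 in cDC2.

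The type I score per library, the mean log2 CPM of the 55 genes, separated the strains without overlap in all 5 cell types. It was 3.98 ± 0.0965 in NOD and 4.72 ± 0.166 in B6g7 cDC1, 4.80 ± 0.0953 and 5.75 ± 0.131 in cDC2, and 5.28 ± 0.219 and 6.01 ± 0.190 in moDC. In each of these the exact permutation p was 0.00216, the smallest possible (adjusted p = 0.00649 over 9 contrasts). In pDC the score was 4.08 ± 0.385 against 4.66 ± 0.145 and in monocytes 5.87 ± 0.0427 against 6.69 ± 0.261, each with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.129). Within sort dates, the list's median change on 10.26.2015 and 01.05.2016 was -0.49 and -0.51 in cDC1, -0.76 and -0.84 in cDC2, and -0.73 and -0.42 in moDC. Each passed camera's test with the preset correlation (adjusted p 1.1e-10, 5.7e-13, 5.3e-20, 6.3e-26, 2.8e-10 and 8.6e-09). Whether the score differed between strains by an unequal amount across the 5 cell types was tested by permuting the residuals of a fit with 1 strain effect, and it did not pass (F = 1.33, permutation p = 0.276, 100000 permutations).

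**Figure D2:**
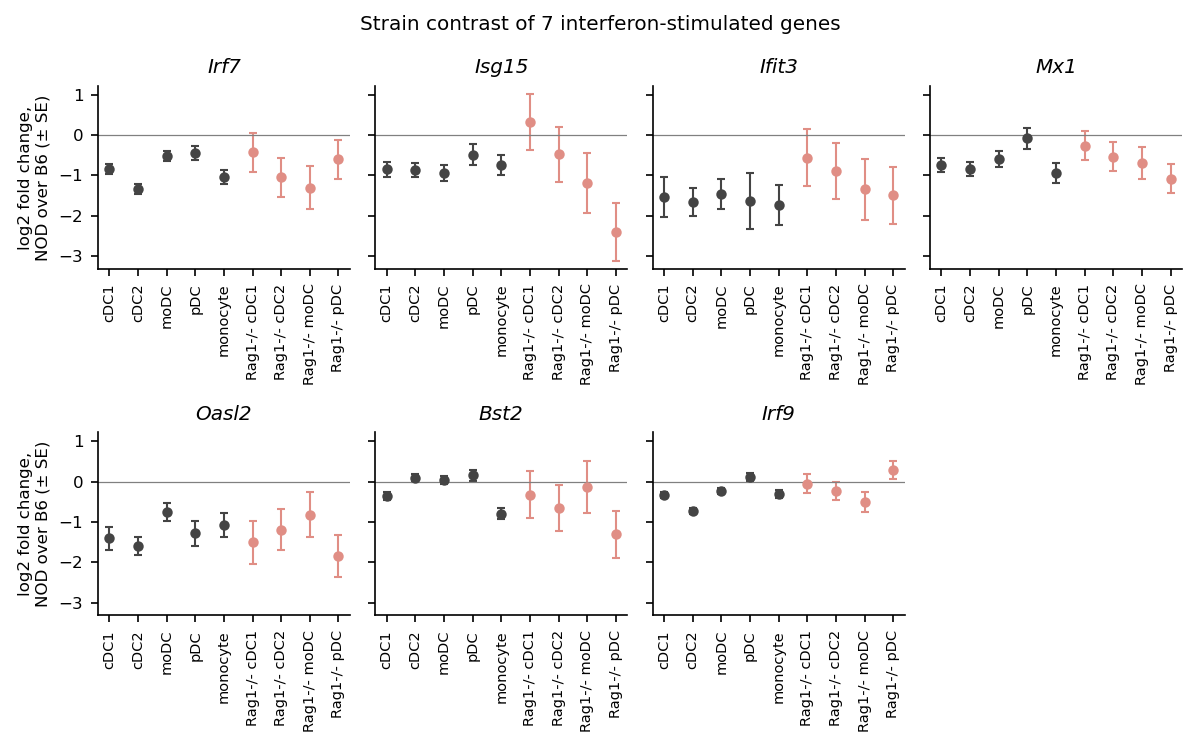
Log2 fold change ± SE (vertical axis) of 7 interferon-response genes, 1 panel each, for NOD against B6g7 (dark points) and NOD Rag1-/- against B6 Rag1-/- (light points) by cell type (horizontal axis). Irf7 ranged from -1.35 in cDC2 to -0.45 in pDC among the Rag-sufficient contrasts, and none of the 7 genes passed the test in Rag1-/- cells.

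In NOD cDC1, 31 of the 55 type I interferon-stimulated genes fell and 1 rose (n = 6 per strain). The RNA sensor Ifih1 went from 21.8 ± 6.52 CPM in B6g7 to 4.83 ± 1.64 in NOD (log2 -2.15 ± 0.25), and the RNA-degradation activators Oas1a and Oas1g fell (log2 -2.32 ± 0.23 and -5.64 ± 1.07). Ifit3b also fell (-3.43 ± 0.71). Irf7, the transcription factor that amplifies interferon production, fell (log2 -0.84 ± 0.12), with Oasl2 (-1.41 ± 0.29), Ifit3 (-1.53 ± 0.49), Isg15 (-0.85 ± 0.19), Mx1 (-0.74 ± 0.18), Bst2 (-0.36 ± 0.10) and Irf9 (-0.34 ± 0.07). The guanylate-binding protein gene Gbp2b rose from 1.66 ± 0.773 to 336 ± 73.4 CPM (log2 7.66 ± 0.32), Gbp3 by 4.69 ± 0.18 and Gbp2 by 3.42 ± 0.17. Il12b, a subunit of the cytokine IL-12, fell from 142 ± 32.8 to 14.5 ± 4.79 CPM (log2 -3.29 ± 0.45), while Il12a rose (4.57 ± 1.245).

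Of 20 cholesterol synthesis genes, 10 fell and 2 rose in cDC1 (11 and 3 adjusted over the list alone), among them Sc5d (log2 -2.03 ± 0.13), Sqle (-1.20 ± 0.21) and Fdft1 (-1.12 ± 0.18). The list's median was -0.43 (camera adjusted p = 1.2e-06; adjusted p = 0.19 with an estimated correlation). The interferon-gamma-associated list had 6 genes up and 5 down of 23, with a mean of 0.34, a median of -0.00 that turns positive without scaling, and a camera adjusted p of 0.44. The remaining 8 gene groups did not pass camera's test (adjusted p 0.13 to 0.90). Within them Calr, a chaperone of MHC class I loading, rose (log2 0.80 ± 0.08), as did H2-Eb2 (1.31 ± 0.17), the kinase gene Ikbke (3.85 ± 0.68) and the T cell costimulatory receptor Cd28 (4.36 ± 0.92). Irak4, a signalling kinase of Toll-like receptors, fell (log2 -1.19 ± 0.16), as did Icos (-2.09 ± 0.26) and the chemokine Ccl17 (-3.16 ± 0.89).

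The largest changes in cDC1 past the threshold without overlap included rises of Ucp1 (log2 7.50 ± 0.98), the carbonic anhydrase Car1 (6.18 ± 1.08), S100a9 (6.18 ± 1.36) and Cpne4 (5.17 ± 0.84). Spint1, an inhibitor of serine proteases, fell from 107 ± 7.63 to 0.157 ± 0.208 CPM (log2 -9.29 ± 0.37), and Apol7c from 1579 ± 328 to 10.5 ± 4.41 CPM (-7.22 ± 0.32). Further falls were of Mcub (-4.45 ± 0.39), Ear2 (-4.33 ± 0.38) and Gcnt1 (-4.23 ± 0.23). In the same libraries markers of other cells were higher in NOD: 9 of 11 B cell markers rose (median log2 3.05), 8 of 10 T cell markers (3.12), 10 of 10 erythroid markers (3.55), 5 of 11 neutrophil markers (4.01) and 2 of 7 plasma cell markers (2.44). Camera's adjusted p for these was 1.7e-05, 8.0e-05, 2.4e-07, 0.0021 and 0.0094, and adjusted p = 0.26 for each with an estimated correlation. The other 7 marker lists did not pass (camera adjusted p 0.27 to 0.92). Cd79a, part of the B cell receptor, was at 93.3 ± 101 CPM in NOD and 5 ± 3.7 in B6g7, and the haemoglobin gene Hbb-bs at 1073 ± 839 and 159.8 ± 176. The edgeR test called 2738 of 13413 genes in cDC1, 1540 higher and 1198 lower in NOD. It called 1513 and 1893 on the separate sort dates, 1141 without a sort date term, and 1424 without the 3 NOD libraries of the highest B cell marker scores, where the type I median was -0.50. These are all NOD cDC1 libraries of 10.26.2015, so this is the other date alone in another form.

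In NOD cDC2, 46 of the 55 type I interferon-stimulated genes fell and the other 9 did not pass the test (n = 6 per strain). Irf7 went from 128 ± 18.3 to 50 ± 7.73 CPM (log2 -1.35 ± 0.13) and Ifit3, an antiviral effector, from 98.5 ± 26.6 to 31.1 ± 8.58 (-1.66 ± 0.35). Oas1g fell (-4.45 ± 0.54), as did Ifi44 (-2.84 ± 0.50), Ifit1 (-1.84 ± 0.39), Ifi27l2a (-1.80 ± 0.25), Oasl2 (-1.59 ± 0.22), Isg15 (-0.86 ± 0.18) and Mx1 (-0.84 ± 0.18). The signalling gene Irf9 (-0.72 ± 0.07) also fell, and Bst2 was at 0.08 ± 0.10 (edgeR adjusted p = 0.61). Irf8, a transcription factor of the cDC1 lineage, rose from 22.5 ± 5.62 to 50 ± 17.7 CPM (log2 1.16 ± 0.15), with Gbp3 (1.52 ± 0.16), Ido1 (1.90 ± 0.54), Ikbke (3.35 ± 0.63) and the costimulatory ligand Cd86 (0.62 ± 0.12). Ccr7, the receptor that guides migrating dendritic cells, fell (log2 -0.64 ± 0.18).

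Of 25 cell cycle genes, 6 fell in cDC2 (7 adjusted over the list alone) and the others did not pass the test, with the mitotic checkpoint gene Bub1b at log2 -1.85 ± 0.32, the replication gene Mcm3 at -0.98 ± 0.15, Aurkb at -0.72 ± 0.19 and Top2a at -0.66 ± 0.23. The list's median was -0.43 (camera adjusted p = 1.9e-04; adjusted p = 0.89 with an estimated correlation). The remaining 9 gene groups did not pass camera's test (adjusted p 0.53 to 0.95). Apart from genes shared by all 5 contrasts, the largest rises without overlap were of Vsx1, from 0.0409 ± 0.0554 to 171 ± 29.6 CPM (log2 11.67 ± 0.40), the phospholipase Pla2g4d (8.72 ± 0.54), Hs3st6 (8.41 ± 0.82) and Rgs16 (7.05 ± 0.76), with Lypd1 at least 1353-fold higher. Falls were led by Apol7c (log2 -9.81 ± 0.43), the sodium channel gene Scn3a (-6.72 ± 0.50), Spint1 (-5.34 ± 0.26) and Cdon (-4.60 ± 0.43), with Skint3 at least 1025-fold lower.

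Markers of other cells moved in cDC2 as well. Of the cDC1 markers 7 of 13 rose (median log2 0.71; camera adjusted p = 3.5e-05; adjusted p = 0.054 with an estimated correlation), among them Gcsam (4.96 ± 0.59) and Cadm1 (1.43 ± 0.16). B cell (9 of 11, median 2.66), T cell (7 of 10, 2.53), NK cell (3 of 11, 2.00), neutrophil (9 of 11, 5.52) and erythroid markers (10 of 10, 3.75) rose, and 3 of 12 red pulp macrophage markers fell (-0.63). For these 6 lists camera's adjusted p was 4.3e-05, 0.0045, 0.034, 4.5e-06, 2.0e-06 and 0.010, and with an estimated correlation adjusted p = 0.29, 0.34, 0.34, 0.098, 0.16 and 0.34. The other 5 marker lists did not pass (camera adjusted p 0.056 to 0.78). The neutrophil granule gene Ngp was at 73.8 ± 74 CPM in NOD and 0.0156 ± 0.0382 in B6g7, and Cd79a at 167 ± 147 and 15.4 ± 12.4. In cDC2 2947 genes passed the edgeR test, 1581 higher and 1366 lower, or 1809 and 971 without scaling. The test called 1682 and 2001 on the separate dates, 1291 without a sort date term, and 1903 without the 3 NOD libraries of the highest B cell marker scores, where the type I median was -0.83.

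In NOD moDC, 41 of the 55 type I interferon-stimulated genes fell and the other 14 did not pass the test (n = 5 NOD and 6 B6g7). Ifih1 went from 50.5 ± 7.57 to 13.2 ± 3.72 CPM (log2 -1.94 ± 0.25) and Ifit3 from 78.3 ± 25.7 to 28.8 ± 11.7 (-1.46 ± 0.37), with Oas1g at -3.81 ± 0.52 and Ifit3b at -1.66 ± 0.40. Isg15 (-0.94 ± 0.20), Oasl2 (-0.76 ± 0.23), Mx1 (-0.59 ± 0.19), Irf7 (-0.52 ± 0.13) and Irf9 (-0.24 ± 0.08) fell, and Bst2 was at 0.03 ± 0.10 (edgeR adjusted p = 0.84). The cytokine Il6 fell from 74.5 ± 88.4 to 3.45 ± 5.72 CPM (log2 -3.72 ± 0.64). Irf8 rose from 134 ± 30.1 to 504 ± 181 CPM (log2 1.78 ± 0.15) with Tlr3, a sensor of double-stranded RNA (1.84 ± 0.28).

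Of 19 costimulation and maturation genes 11 fell and 2 rose in moDC, with the chemokine Ccl22 at log2 -1.46 ± 0.42, the cytokine Il15 at -1.28 ± 0.23 and the actin-bundling gene Fscn1 at -1.15 ± 0.26. The list's median was -0.73 (camera adjusted p = 0.0095; adjusted p = 0.094 with an estimated correlation). NF-kB and inflammatory genes had 10 down and 3 up of 25 (median -0.13), with the chemokine Ccl4 at -1.88 ± 0.40 and Cxcl2 at 1.87 ± 0.50. MHC class II genes had 6 down and 2 up of 15 (-0.21), with H2-Eb2 at -1.27 ± 0.17 and H2-Oa at -0.88 ± 0.12. Immediate early genes had 5 down of 21 (-0.30), with Ier3 at -1.250 ± 0.24. Cholesterol synthesis genes had 7 up and 2 down of 20 (0.39), with the sterol sensor partner Insig1 at 1.43 ± 0.12 and Dhcr7 at 0.91 ± 0.17. Adjusted over the list alone, all 5 lists gave the same numbers. For the last 4 camera's adjusted p was 0.033, 0.045, 0.023 and 0.027, and with an estimated correlation adjusted p = 0.41, 0.44, 0.44 and 0.44. Each of these 4 calls ended without some single library, with camera adjusted p of up to 0.061, 0.0997, 0.061 and 0.081. Without scaling the MHC class II call also ended (median -0.08, camera adjusted p = 0.11). The NF-kB and immediate early medians were then -0.00051 and -0.17, and both lists still passed (camera adjusted p 0.025 and 0.024). The remaining 5 gene groups did not pass camera's test (adjusted p 0.10 to 0.95), and within them Cd93 rose (log2 3.37 ± 0.37).

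Apart from genes shared by all 5 contrasts, the largest rises without overlap in moDC were of the neutrophil granule genes Ngp (log2 11.64 ± 1.68) and Ltf (6.94 ± 1.04), of Vsx1 (7.59 ± 0.40) and of Angptl7 (7.35 ± 0.49), and Camp was at least 1594-fold higher. Skint3 was at least 3050.0-fold lower, and Apol7c (-9.89 ± 0.48), Guca1a (-7.10 ± 0.70), Spint1 (-6.99 ± 0.32) and Tcea3 (-3.73 ± 0.48) fell. Of the cDC1 markers 11 of 13 rose and 1 fell (median 1.72; camera adjusted p = 4.8e-08; adjusted p = 0.0036 with an estimated correlation), with the chemokine receptor Xcr1 going from 7.54 ± 4.54 to 48.5 ± 9.2 CPM. B cell (11 of 11, median 2.81), T cell (8 of 10, 2.89), neutrophil (9 of 11, 4.58), erythroid (10 of 10, 3.17), plasma cell (6 of 7, 2.85) and red pulp macrophage markers (5 of 12, 0.94) rose. For these 6 lists camera's adjusted p was 1.7e-06, 2.7e-04, 3.6e-06, 1.7e-06, 9.2e-05 and 0.014, and with an estimated correlation adjusted p = 0.12, 0.13, 0.096, 0.12, 0.096 and 0.38. The other 5 marker lists had camera adjusted p of 0.059 to 0.83. In moDC 4071 genes passed the edgeR test, 2148 higher and 1923 lower. The split was 3020 and 1221 without scaling, which moved the median of all genes by 0.12. The test called 2734 and 3045 on the separate dates, 1637 without a sort date term and 2690 in a fit of moDC alone.

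In NOD pDC, 16 of the 55 type I interferon-stimulated genes fell and 3 rose (n = 3 per strain). Oas1a fell from 13.1 ± 4.04 to 2.16 ± 1.55 CPM (log2 -2.57 ± 0.32), with the interferon-induced chaperone Rtp4 (-2.23 ± 0.55), Parp12 (-2.22 ± 0.41) and Oasl2 (-1.28 ± 0.32), and Oas1g was at 0.519 CPM in B6g7 with no count in NOD. Ifit3 (-1.63 ± 0.70), Isg15 (-0.48 ± 0.26), Irf7 (-0.45 ± 0.17), Mx1 (-0.08 ± 0.26), Irf9 (0.11 ± 0.10) and Bst2 (0.15 ± 0.14) did not pass the test. Of 23 interferon-gamma-associated genes 9 fell, with the chemokines Cxcl9 (log2 -3.21 ± 0.95) and Cxcl10 (-2.32 ± 0.66) and the protease inhibitor Serpina3g, which went from 44.9 ± 10.4 to 7.61 ± 1.51 CPM. Of 19 costimulation and maturation genes 9 fell (12 adjusted over the list alone), with Ccr7 going from 40.4 ± 2.91 to 5.41 ± 2.25 CPM (log2 -2.90 ± 0.30), Cd80 at -3.58 ± 0.64 and Pdcd1lg2 at -2.69 ± 0.67.

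The medians in pDC were -0.65 for the interferon-gamma-associated list and -1.14 for costimulation, and both calls held with an estimated correlation (camera adjusted p 9.8e-07 and 3.0e-07; adjusted p = 0.023 and 9.6e-04 with an estimated correlation). NF-kB and inflammatory genes had 10 down and 1 up of 25 (13 and 1 over the list alone; median -0.45), with Il12b (-6.60 ± 1.69), the prostaglandin synthase Ptgs2 (-5.53 ± 1.18) and Ccl5 (-2.31 ± 0.48), and Il1a at least 42.3-fold lower. MHC class II genes had 7 down of 15 (8 over the list alone; -0.29), with H2-Ob (-1.82 ± 0.42) and Ifi30 (-0.78 ± 0.12). Diabetes-locus candidate genes had 6 down and 1 up of 18 (-0.49), with Fcgr1 (-3.76 ± 0.86), which is also in the monocyte and macrophage marker list, Icos (-3.46 ± 0.70) and the metal transporter Slc11a1 (-2.79 ± 0.52). These calls also held (camera adjusted p 1.1e-05, 1.2e-05 and 0.011; adjusted p = 0.021, 0.041 and 0.023 with an estimated correlation). Macrophage markers were also lower in these NOD libraries, as given below. Whether fewer macrophages account for the lower gene groups was not tested. MHC class I genes had 8 down and 1 up of 18 (9 and 1 over the list alone; -0.25), with H2-Q7 at -1.34 ± 0.17 and Calr at 0.60 ± 0.11 (camera adjusted p = 0.0027; adjusted p = 0.14 with an estimated correlation). The remaining 4 gene groups did not pass camera's test (adjusted p 0.082 to 0.81), and within them Slc15a4, a lysosomal transporter needed for Toll-like receptor signalling in pDC, rose (log2 0.85 ± 0.17).

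The largest rises without overlap in pDC included Rora, a nuclear receptor, from 5.23 ± 0.3 to 211 ± 3.7 CPM (log2 5.34 ± 0.30), Cybrd1 (7.15 ± 0.96), Eps8 (6.60 ± 0.31), Hal (6.00 ± 1.11) and Nrip2 (5.58 ± 0.58). The CD8 subunit gene Cd8b1 fell from 1047 ± 290.4 to 32.1 ± 6.43 CPM (log2 -5.02 ± 0.60), with H2bu2 (-8.85 ± 1.01), the efflux pump Abcb1b (-8.66 ± 0.80) and Treml2 (-8.04 ± 0.99), and Ear2 was at least 169-fold lower. The surface markers Ly6d (-3.40 ± 0.74) and Ly6c2 (-2.66 ± 0.58) fell and Cadm1 rose (3.22 ± 0.22), while the pDC marker list as a whole had a camera adjusted p of 0.51. Red pulp macrophage markers fell in 12 of 12 (median -2.52) and monocyte and macrophage markers in 6 of 14 with 1 up (-1.39), with C1qc going from 118 ± 12 to 18.3 ± 3.16 CPM and Lyz2 from 123 ± 123 to 8.22 ± 3.77. Of 10 erythroid markers 5 rose (3.72). For the 3 lists camera's adjusted p was 1.6e-10, 8.4e-05 and 9.3e-07, and with an estimated correlation adjusted p = 0.11, 0.15 and 0.15. The other 9 marker lists had camera adjusted p of 0.069 to 0.90, among them B cell markers at a median of -2.54 (0.069) and NK cell markers at -2.15 (0.28). In pDC 1684 genes passed the edgeR test, 691 higher and 993 lower. All pDC were sorted on 1 date, and the count was 597 in the joint fit without a sort date term.

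In NOD monocytes, 36 of the 55 type I interferon-stimulated genes fell and 1 rose (n = 3 per strain). Irf7 went from 407 ± 78.9 to 199 ± 11.8 CPM (log2 -1.03 ± 0.17), Oas1g from 43.5 ± 21.9 to 2.72 ± 0.85 (-4.00 ± 0.67) and Oas3 from 108 ± 30.1 to 29.6 ± 1.27 (-1.87 ± 0.38). Ifih1 (-1.87 ± 0.32), Ifit3 (-1.73 ± 0.49), Oasl2 (-1.08 ± 0.30), Mx1 (-0.95 ± 0.25), Bst2 (-0.80 ± 0.14), Isg15 (-0.74 ± 0.26) and Irf9 (-0.31 ± 0.10) fell. Of 18 MHC class I presentation genes 12 fell and 3 rose (13 and 3 over the list alone), with H2-Q7 going from 90 ± 29.7 to 20.1 ± 5.5 CPM. H2-K1 was at log2 -0.94 ± 0.11, H2-D1 at -0.73 ± 0.10 and Calr at 0.79 ± 0.11. Egr1, a growth and differentiation transcription factor, rose from 94.4 ± 3.3 to 531 ± 70.4 CPM (log2 2.49 ± 0.18).

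The MHC class I list's median in monocytes was -0.42 (camera adjusted p = 2.3e-05; adjusted p = 0.080 with an estimated correlation). NF-kB and inflammatory genes had 8 up and 1 down of 25 (9 and 1 over the list alone; median 0.39), with Cxcl2 (1.98 ± 0.67) and the inflammasome gene Nlrp3 (0.87 ± 0.25) up and Ccl5 (-2.60 ± 0.63) down. Cholesterol synthesis genes had 9 up and 1 down of 20 (0.43), with Insig1 (1.14 ± 0.16) and Sc5d (-1.20 ± 0.18). Camera's adjusted p was 0.016 and 0.0019, and with an estimated correlation adjusted p = 0.26 and 0.28. Without B6g7 2 the NF-kB list had a camera adjusted p of 0.097. The remaining 7 gene groups did not pass camera's test (adjusted p 0.082 to 0.50), and within them Cd93 rose (2.29 ± 0.45) and the phosphatase Ptpn22 fell (-0.58 ± 0.17).

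Apart from genes shared by all 5 contrasts, the largest rises without overlap in monocytes were of the ribonucleases Ear1 (log2 8.71 ± 0.82) and Ear10 (6.77 ± 0.75), Emp1 (5.80 ± 0.74), Cd72 (5.58 ± 0.50) and Clmn (5.23 ± 0.89). The falls were led by neutrophil granule genes: Camp was at least 7557-fold lower, Ngp went from 1149 ± 894 to 0.0362 ± 0.0627 CPM and Ltf from 317 ± 255 to 0.13 ± 0.0636. Skint3 was at least 754-fold and Itgb2l at least 242-fold lower, and the monocyte marker Ly6c2 fell from 2000.0 ± 199.8 to 281 ± 4.61 CPM. Of the same gene family, Ly6c1 was higher in NOD in all 5 Rag-sufficient contrasts (log2 2.51 to 6.21) and Ly6i lower (-6.40 to -3.25). Whether reads of 1 of these genes were assigned to another was not tested. Of 11 neutrophil markers 6 fell (median -6.03; camera adjusted p = 2.5e-05; adjusted p = 0.25 with an estimated correlation), and erythroid markers had a median of 2.49 with 1 of 10 past the test (camera adjusted p = 8.2e-05; adjusted p = 0.50 with an estimated correlation). The other 10 marker lists did not pass (camera adjusted p 0.23 to 0.81). In monocytes 2057 genes passed the edgeR test, 1048 higher and 1009 lower. The count was 617 in the joint fit without a sort date term.

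**Figure D3:**
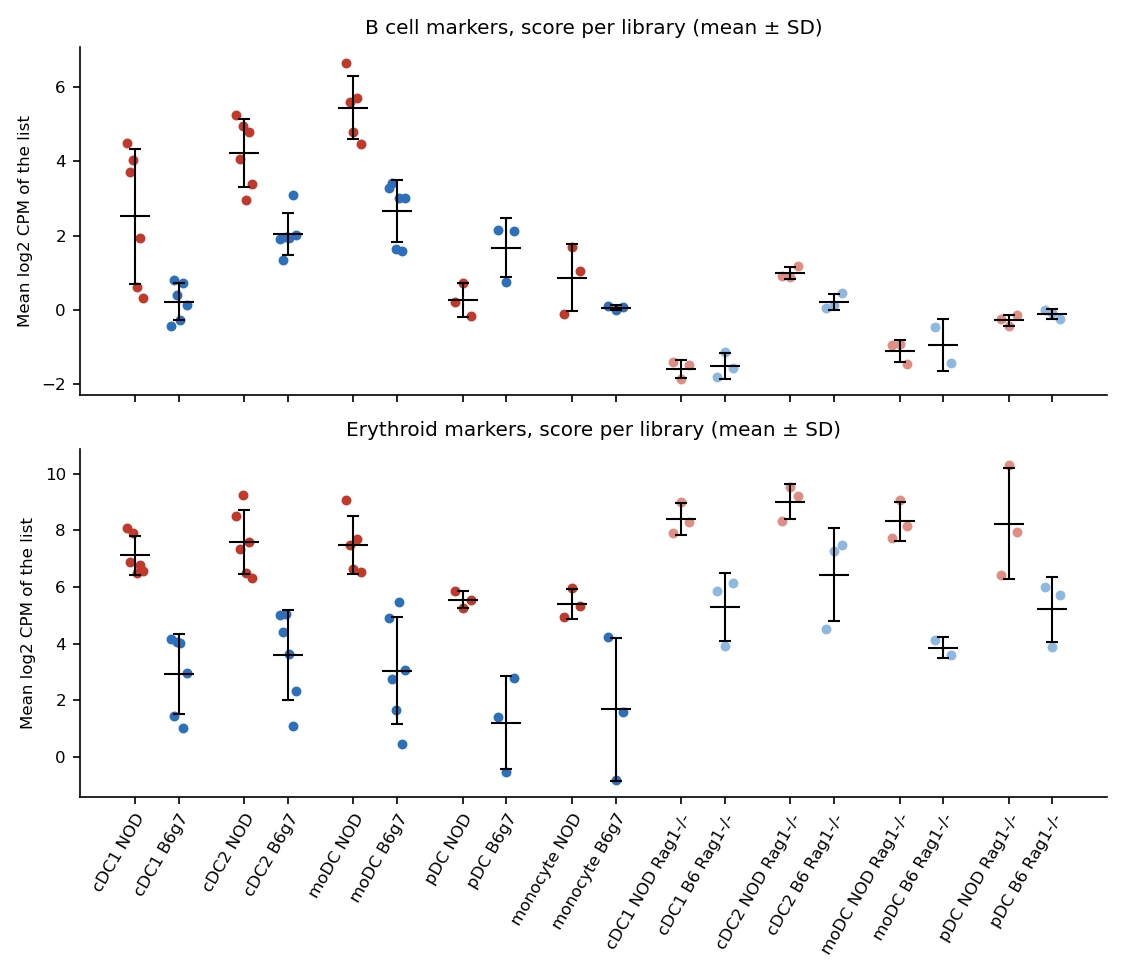
Mean log2 CPM per library (vertical axes, points) of the B cell markers (upper panel) and the erythroid markers (lower panel) by cell type, strain and genotype (horizontal axis), with lines for the group mean ± SD. In moDC the B cell score was 5.45 ± 0.856 in NOD, 2.67 ± 0.823 in B6g7 and -1.10 ± 0.293 in NOD Rag1-/-, and the erythroid score 7.48 ± 1.03, 3.06 ± 1.91 and 8.32 ± 0.694.

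Of the genes tested, 322 were past the threshold with 1 sign in all 5 Rag-sufficient contrasts, 138 higher and 184 lower in NOD, where independent contrasts would share 0.214. They included Trim12a, a TRIM-family gene (log2 -9.22 to -7.14), and the haem-binding protein gene Hebp1 (4.25 to 7.78). The others most significant by the weakest contrast were Gnpda1 (log2 -2.41 in cDC1), Zfp979 (9.39), the ubiquitin gene Ubb (-1.77), Rpl29 (-3.13), Cap1 (1.93), Zfp985, at least 163-fold higher in cDC1, Srp9 (-1.26) and the histone gene H4c4 (-3.41). Some pseudogenes among the 322 moved against their gene. Ubb was at -1.805 to -1.539 and Ubb-ps at 2.561 to 3.591, Ndufs5 at -5.464 to -4.523 and Ndufs5-ps at 0.598 to 0.872. Rpl34 and Rpl34-ps1 were both lower. Whether strain variants moved reads between such copies was not tested. An F test of equal strain effects in the 5 cell types called 3264 genes. When the Rag1-/- contrasts were added, 57 of 12869 genes tested in both sets were called with 1 sign in all 9, 26 higher and 31 lower, and 13 when each cell type was fitted separately. Trim12a, Zfp979, Rmnd1, St6galnac1, the interferon-inducible gene Ifi202b, Ahcy, Ndufs5, Timmdc1, Tmem14c and Tnfrsf14 led these. Ifi202b ranged from 6.92 to 13.99 and Trim12a from -9.97 to -7.14.

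**Figure D4:**
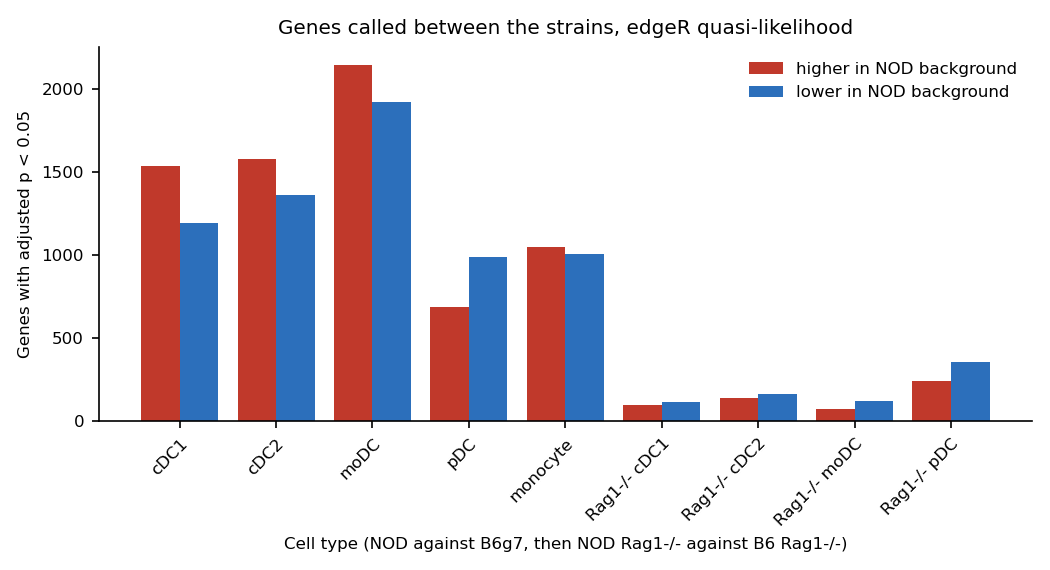
Number of genes past an edgeR adjusted p of 0.05 (vertical axis), higher (red bars) and lower (blue bars) in NOD, in each strain contrast (horizontal axis). Totals were 1684 (pDC) to 4071 (moDC) in the Rag-sufficient contrasts and 196 (moDC) to 602 (pDC) in the Rag1-/- contrasts.

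The comparison of NOD Rag1-/- with B6 Rag1-/- asks a like question of mice without B and T cells, but its controls are not B6g7. With scaling over all libraries, cDC1 held H2-T23 at 111 CPM in B6g7 and 752 in B6 Rag1-/-, and H2-Q2 at 47.4 and 0. Changes of MHC genes in this set thus cannot be told apart from a difference between the controls. In cDC1 the sensor Ifih1 fell from 32.5 ± 11.1 to 8.47 ± 0.579 CPM (log2 -1.94 ± 0.29; n = 3 per strain), the only one of the 55 type I interferon-stimulated genes past the test. Gbp2b rose from 7.27 ± 4.51 to 504 ± 243 CPM (log2 6.11 ± 0.93), with Gbp2 (3.79 ± 0.61) and Gbp3 (3.56 ± 0.45). MHC genes differed in both directions: H2-Q2 was at least 352-fold higher in NOD and H2-Q1 rose (log2 7.18 ± 0.74). H2-DMb2 rose (1.75 ± 0.39), while H2-T23 fell from 798 ± 27.2 to 74.6 ± 9.1 CPM and H2-K1 from 2378 ± 92.8 to 709 ± 67.8. Irf7 was at log2 -0.43 ± 0.48, Ifit3 at -0.56 ± 0.70, Isg15 at 0.33 ± 0.69, Mx1 at -0.26 ± 0.35, Oasl2 at -1.504 ± 0.53, Bst2 at -0.33 ± 0.58 and Irf9 at -0.05 ± 0.23, none past the test.

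Spint1 (-10.02 ± 0.84), Apol7c (-8.62 ± 0.82), the Fc receptor-like genes Fcrlb (-8.58 ± 1.496) and Fcrla (-5.41 ± 0.70) and Ear2 (-5.29 ± 0.92) were the largest falls in Rag1-/- cDC1 apart from genes shared by the 5 Rag-sufficient contrasts. Among the rises were Ucp1 (8.45 ± 1.79) and Reck (4.89 ± 1.13). The type I median was -0.07 with a mean of -0.28 (camera adjusted p = 0.44), and the other 10 gene groups did not pass either (adjusted p 0.44 to 0.89), though Irak4 (-2.56 ± 0.29), the adaptor of DNA sensing Sting1 (-1.29 ± 0.30) and Sc5d (-1.68 ± 0.30) fell. Erythroid markers had a median of 2.72, with 10 of 10 higher over the list alone (camera adjusted p = 6.8e-11; adjusted p = 0.23 with an estimated correlation). NK cell markers were at -2.19 and pDC markers at -0.50 with a mean of -0.14 (camera adjusted p 0.0099 and 0.044; adjusted p = 0.53 for each with an estimated correlation). The other 9 marker lists did not pass (camera adjusted p 0.11 to 0.84). The edgeR test called 219 of 13137 genes, 101 higher and 118 lower. The replicate numbers pair the strains by sort date here, and 88 were called with the pairs as a block. With that block Gbp2, H2-K1, H2-DMb2, Ucp1, Reck, Ear2 and Sting1 no longer passed (edgeR adjusted p 0.077, 0.077, 0.17, 0.071, 0.079, 0.077 and 0.14). The cDC2 markers, at a median of -0.54, then passed camera's test (median -0.76 and adjusted p = 0.040 with the block).

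In Rag1-/- cDC2, 4 of the 55 type I interferon-stimulated genes fell (8 over the list alone; n = 3 per strain): Ifih1 (log2 -2.31 ± 0.30), Trim25 (-1.29 ± 0.27), which activates the RNA sensor RIG-I, Trim30d (-1.15 ± 0.26) and the kinase Eif2ak2 (-1.02 ± 0.26). Irf7 was at -1.04 ± 0.49, Oasl2 at -1.19 ± 0.51, Ifit3 at -0.88 ± 0.69, Mx1 at -0.53 ± 0.36, Isg15 at -0.47 ± 0.68, Bst2 at -0.65 ± 0.58 and Irf9 at -0.23 ± 0.23, none past the test. H2-T23 fell from 744 ± 25.2 to 78.8 ± 15.3 CPM and H2-K1 from 2496 ± 151 to 471 ± 43, while H2-Q1 rose (log2 9.11 ± 0.87). Vsx1 was at least 3108-fold, Pla2g4d at least 1670.0-fold, Lypd1 at least 308-fold and H2-Q2 at least 268-fold higher. Apol7c was at least 2227-fold and Skint3 at least 783-fold lower, and Slc7a2 (-8.87 ± 1.86), Vnn3 (-7.14 ± 1.51), Matn2 (-6.17 ± 0.82), Slc11a1 (-2.49 ± 0.56) and the lectin Clec12a (-3.07 ± 0.56) fell.

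The type I median in Rag1-/- cDC2 was -0.73 (camera adjusted p = 8.9e-11; adjusted p = 0.67 with an estimated correlation), and MHC class I genes had a median of -0.20 with 2 of 18 down (camera adjusted p = 0.039; adjusted p = 0.67 with an estimated correlation), or -0.09 without NOD Rag1-/- 2 (camera adjusted p = 0.15). The other 9 gene groups did not pass camera's test (adjusted p 0.31 to 0.89). Medians were -2.17 for red pulp macrophage markers (9 of 12 lower over the list alone), -3.15 for NK cell, -0.85 for monocyte and macrophage, 0.90 for neutrophil and 2.19 for erythroid markers. Camera's adjusted p was 7.3e-06, 1.5e-04, 0.037, 0.0085 and 1.3e-06, and adjusted p = 0.46 for each with an estimated correlation. The other 7 marker lists had camera adjusted p of 0.14 to 0.86. In all, 307 genes passed the edgeR test, 141 higher and 166 lower. The count was 565 in a fit of cDC2 alone and 179 without NOD Rag1-/- 2, the lowest when 1 library was left out.

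In Rag1-/- moDC, Ifih1 fell from 112 ± 16.1 to 20.1 ± 4.24 CPM (log2 -2.48 ± 0.32; n = 3 NOD and 2 B6) and Trim30d fell (log2 -1.23 ± 0.28), the only 2 of the 55 type I genes that passed the test (3 fell over the list alone). Irf7 was at -1.30 ± 0.53, Ifit3 at -1.35 ± 0.76, Isg15 at -1.18 ± 0.75, Oasl2 at -0.82 ± 0.56, Mx1 at -0.69 ± 0.39, Irf9 at -0.50 ± 0.25 and Bst2 at -0.13 ± 0.64, none past the test. Of 15 MHC class II genes 3 fell (4 over the list alone), H2-Oa (-2.47 ± 0.52), H2-DMb1 (-1.63 ± 0.37) and H2-Ob (-1.52 ± 0.38), and of 18 MHC class I genes 2 fell, H2-T23 (-4.00 ± 0.36) and H2-K1 (-2.08 ± 0.32). Cd93 (2.80 ± 0.69), Angptl7 (7.11 ± 1.36), H2-Q1 (7.05 ± 0.87), Ear10 (6.84 ± 1.31) and the globin Cygb (6.31 ± 0.86) rose, and H2-Q2 was at least 261-fold higher. Skint3 was at least 2350.0-fold lower, and Apol7c (-10.91 ± 1.01), Spint1 (-9.25 ± 0.80), Vnn3 (-6.40 ± 1.52), the stem cell antigen gene Ly6a (-4.36 ± 0.83) and Icos (-2.70 ± 0.67) fell.

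The type I median in Rag1-/- moDC was -0.55 (camera adjusted p = 6.0e-06; adjusted p = 0.44 with an estimated correlation), and 0.10 without B6 Rag1-/- 2. Medians were -0.84 for costimulation, -0.62 for MHC class II, -0.08 for MHC class I, 0.54 for cell cycle and -0.47 for immediate early genes. Camera's adjusted p was 2.9e-04, 2.9e-04, 0.018, 0.0048 and 0.0018, and with an estimated correlation adjusted p = 0.15, 0.44, 0.44, 0.65 and 0.44. Without B6 Rag1-/- 2 the MHC class I median was 0.14 and that of cell cycle 0.04 (camera adjusted p = 0.70 and 0.95). Immediate early genes were at -0.26 without NOD Rag1-/- 1 (camera adjusted p = 0.14). The other 5 gene groups did not pass (camera adjusted p 0.088 to 0.57), nor did 9 marker lists (0.083 to 0.63). Erythroid markers had a median of 4.62 (3 of 10 up; 10 of 10 over the list alone), neutrophil markers 3.79 and NK cell markers -2.20 (camera adjusted p 2.6e-16, 4.1e-04 and 6.2e-06; adjusted p = 0.068, 0.44 and 0.40 with an estimated correlation). In all, 196 genes passed the edgeR test, 75 higher and 121 lower, and 81 passed without B6 Rag1-/- 1.

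In Rag1-/- pDC, 3 of the 55 type I interferon-stimulated genes fell (11 over the list alone; n = 3 per strain): the membrane antiviral gene Ifitm3 (log2 -3.02 ± 0.81), the nucleic acid sensor Zbp1 (-2.63 ± 0.69) and Ifih1 (-1.92 ± 0.30). Isg15 was at -2.40 ± 0.72, Oasl2 at -1.84 ± 0.52, Ifit3 at -1.49 ± 0.72, Bst2 at -1.31 ± 0.59, Mx1 at -1.08 ± 0.36, Irf7 at -0.60 ± 0.48 and Irf9 at 0.28 ± 0.23, none past the test. The interferon-gamma-associated list had 4 of 23 down, with Cxcl10 (-3.45 ± 0.79) and Cxcl9 (-3.38 ± 0.78). MHC class I genes had 3 of 18 down (9 over the list alone), with H2-T23 going from 2220.0 ± 766 to 137 ± 69.1 CPM, and MHC class II genes 5 of 15 (7 over the list alone), with H2-Ob (-3.32 ± 0.38). Of 25 cell cycle genes 2 rose (18 over the list alone), the mitotic kinase Plk1 (3.81 ± 1.07) and the nucleotide synthesis gene Rrm2 (3.71 ± 1.02). The cell cycle score was 6.90 in NOD Rag1-/- 2, against 3.35 and 3.46 in the other NOD and 2.32 to 3.95 in the B6 libraries. Its erythroid score was also the highest, at 10.32 against 6.42 and 7.95 in the other NOD libraries. In cDC1, cDC2 and moDC too, the NOD Rag1-/- library of 02.02.2015 had the highest cell cycle and erythroid scores of its group. The B6 Rag1-/- cDC1 and cDC2 libraries of that date had the highest cell cycle but the lowest erythroid score. Whether the scores are linked was not tested. The costimulatory receptor Cd40 (-2.28 ± 0.45), Abcb1b (-10.30 ± 1.03), Apod (-6.03 ± 1.12), Sct (-5.87 ± 1.29), Cd8b1 (-5.61 ± 0.98), D17H6S56E-5 (-5.39 ± 0.74) and Ly6d (-5.08 ± 1.05) fell. H2-Q2 (7.65 ± 0.60), H2-Q1 (7.02 ± 0.73), Pdzk1ip1 (6.11 ± 1.62) and Ank1 (5.53 ± 1.26) rose, and Gbp2b was at least 224-fold higher.

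The medians in Rag1-/- pDC were -0.76 for type I genes, -0.51 for interferon-gamma-associated, -0.76 for NF-kB, -0.88 for MHC class I, -0.95 for MHC class II, -0.65 for costimulation, 2.20 for cell cycle and -0.55 for immediate early genes. Camera's adjusted p was 4.2e-06, 0.0027, 0.0021, 1.9e-04, 7.0e-04, 0.037, 4.0e-06 and 0.042, and with an estimated correlation adjusted p = 0.42, 0.46, 0.42, 0.42, 0.42, 0.42, 0.43 and 0.49. Without NOD Rag1-/- 2 the cell cycle median was 0.10 (camera adjusted p = 0.16). Without B6 Rag1-/- 3 the interferon-gamma-associated, NF-kB, costimulation and immediate early lists no longer passed (camera adjusted p 0.071, 0.088, 0.10 and 0.54). Without scaling all 8 lists passed, at medians of -0.26, -0.05, -0.39, -0.38, -0.43, -0.18, 2.66 and -0.22. The other 3 gene groups did not pass (camera adjusted p 0.12 to 0.51), nor did 10 marker lists (0.069 to 0.87). Erythroid markers were at 3.40 (6 of 10 up) and NK cell markers at -1.84 (camera adjusted p 1.6e-06 and 0.0019; adjusted p = 0.72 for each with an estimated correlation). In all, 602 genes passed the edgeR test, 246 higher and 356 lower. Without scaling the split was 418 and 158 and the median of all genes moved by 0.43. The count was 85 in a fit of pDC alone, and leaving out 1 library gave between 246 and 3183.

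Strain differences in the Rag1-/- set were compared with those of the Rag-sufficient set, which share no library. In cDC1, cDC2, moDC and pDC, 90, 121, 66 and 143 genes were higher in NOD in both sets and 105, 124, 102 and 242 lower. Independent calls would give 11.6, 16.2, 11.9 and 12.9 higher and 10.7, 16.9, 17.7 and 26.9 lower. Opposite calls numbered 3, 3, 1 and 7. The log2 changes correlated across genes, which are not independent replicates, with r of 0.604, 0.604, 0.628 and 0.431.

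Whether the strain effect itself differed between the sets was tested as the Rag-sufficient change minus the Rag1-/- change. In cDC1 the non-classical MHC gene H2-T23 was at 107 and 111 CPM in NOD and B6g7 and at 70.6 and 752 in NOD Rag1-/- and B6 Rag1-/- (difference of log2 changes 3.38 ± 0.25, edgeR adjusted p = 9.8e-16). H2-Q1 was at 30.0, 25.6, 14.99 and 0.104 CPM in the same groups (-6.97 ± 0.45, edgeR adjusted p = 5.1e-18). H2-T10 (-2.45 ± 0.25), H2-T24 (-2.10 ± 0.29), H2-Q5 (3.36 ± 0.48), H2-T22 (3.08 ± 0.29), D17H6S56E-5 (3.16 ± 0.52) and Hebp1 (2.85 ± 0.62) also differed, and H2-Q2 was at 51.9, 47.4, 19.8 and 0 CPM. In cDC2 the largest positive differences were of G0s2 (10.58 ± 1.76), Matn2 (5.34 ± 1.32), Rnase4 (5.31 ± 1.00), Gimap4 (4.89 ± 1.13) and Cd2 (4.60 ± 1.23). The negative ones were of H2-Q2 (at 30.1, 40.7, 12.5 and 0 CPM), H2-Q1 (-9.28 ± 0.53), Mdk (-4.00 ± 1.08), Crispld2 (-3.32 ± 0.89) and Ryr3 (-2.76 ± 0.70). In moDC the positive ones were of the B cell gene Ms4a1 (6.28 ± 1.21), the T cell receptor gene Cd247 (7.71 ± 1.19), Ly6a (4.24 ± 0.73), Hepacam2 (4.21 ± 0.64) and Fcrla (4.04 ± 1.02). On the negative side were those of H2-Q2 (at 35.6, 38.3, 19.9 and 0 CPM), H2-Q1 (-7.20 ± 0.50), Cd63 (-2.83 ± 0.70), H2-T10 (-2.55 ± 0.28) and Pglyrp1 (-2.51 ± 0.63).

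In pDC H2-T23 was at 129, 156, 127 and 2042 CPM (difference 3.73 ± 0.28, edgeR adjusted p = 5.3e-15). Cd59a (5.06 ± 0.88), Apod (4.11 ± 1.11), H2-Q5 (4.09 ± 0.57) and D17H6S56E-5 (3.88 ± 0.63) also differed. The negative differences were of H2-Q2 (-8.42 ± 0.52), H2-Q1 (-7.69 ± 0.48), the lysozyme gene Lyz2 (-5.74 ± 0.84), Cdc6 (-5.70 ± 1.22) and Hmgb3 (-4.80 ± 1.07). The edgeR test called 29 genes in cDC1, 154 in cDC2, 81 in moDC and 187 in pDC of 13837. Of these, 19, 21, 19 and 36 lie on chromosome 17, which holds the MHC and 5.39% of the genes tested. The type I list's difference was -0.44 in cDC1 (camera adjusted p = 8.2e-14; adjusted p = 0.21 with an estimated correlation), -0.20 in cDC2, 0.02 in moDC and 0.22 in pDC (camera adjusted p 0.16, 0.12 and 0.099). Without single libraries the count ranged from 49 to 350 in cDC2 and from 88 to 2868 in pDC.

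**Figure D5:**
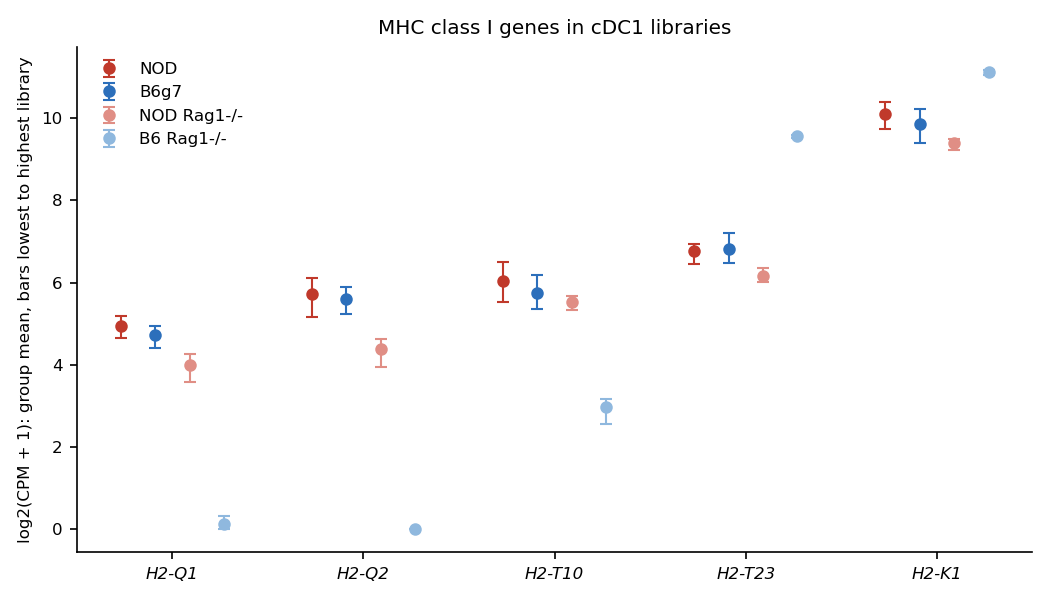
Log2 of CPM + 1 (vertical axis) of 5 MHC class I genes (horizontal axis) in cDC1 of the 4 groups, with points for the group mean and bars from the lowest to the highest library. H2-T23 was at 752 CPM on average in B6 Rag1-/- and between 70.6 and 111 in the other groups.

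The type I score was also compared between NOD Rag1-/- and NOD and between B6 Rag1-/- and B6g7. Genotype cannot be told apart there from sequencing run, sort date and cell number, nor, between B6 Rag1-/- and B6g7, from strain. In NOD it was higher in Rag1-/- by 0.948 log2 in cDC1, 0.880 in cDC2 (for each of these exact permutation p = 0.0119, adjusted p = 0.0317), 1.05 in moDC (exact permutation p = 0.0179, adjusted p = 0.0357) and 0.985 in pDC (exact permutation p = 0.1, adjusted p = 0.114). In B6 Rag1-/- it was higher than in B6g7 by 0.301 in cDC1 (exact permutation p = 0.214), 0.705 in cDC2 (0.0119, adjusted p = 0.0317), 0.848 in moDC (0.0714, adjusted p = 0.114) and 1.19 in pDC (0.1). Within the Rag1-/- set the score of NOD and B6 was 4.93 and 5.02 in cDC1 (exact permutation p = 1), 5.68 and 6.45 in cDC2 and 5.06 and 5.85 in pDC (0.1 each, the smallest that 3 against 3 allow), and 6.33 and 6.86 in moDC (0.4).

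The authors' comparison tables, counted here at the same threshold per transcript, held 2388, 2723, 3678, 1785 and 1771 transcripts for Rag-sufficient cDC1, cDC2, moDC, pDC and monocytes, and 492, 685, 503 and 1016 for Rag1-/- cDC1, cDC2, moDC and pDC. Their log2 changes had the sign of the fits here for 95.9%, 96.0%, 96.3%, 94.7%, 96.6%, 91.1%, 93.1%, 92.2% and 91.3% of the transcripts compared. Of these, 84.5%, 79.7%, 84.4%, 66.8%, 78.7%, 44.6%, 48.3%, 38.1% and 46.4% were called here too. Of the type I genes the tables held 14, 35, 27, 2 and 25 as lower in the Rag-sufficient contrasts, where 31, 46, 41, 16 and 36 fell here.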

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

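Of the tests in this part, those of sort date and the counts in 10 or 100 groupings of the libraries were fixed before their results were seen, and all others, with the counts in 400 groupings, were chosen after the pattern they test had been seen.

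The first pattern is the lower type I list in Rag-sufficient NOD cells. Whether it needs the B and T cells that Rag1-/- mice lack stays open: within the Rag1-/- set the medians were -0.07 in cDC1, -0.73 in cDC2, -0.55 in moDC (0.10 without B6 Rag1-/- 2) and -0.76 in pDC (-0.26 without scaling), the last 3 past camera's test but not with an estimated correlation, and the cDC2 scores did not overlap (5.40 to 5.87 in NOD, 6.15 to 6.68 in B6). Sort date does not account for it, since the highest of the 6 within-date medians was still -0.42. Cells of other types in the NOD sorts would lower the sorted cells' own markers as much as the interferon list. In cDC1 the gap between the 2 medians was 0.595 (SE 0.219), past a bound of 2 SE. The gaps of 0.722, 0.400 and 0.570 in cDC2, pDC and monocytes (SE 0.403, 0.428 and 0.308) were not, with 0.3999 as the smallest. These were at first 1 test with 1 bound, met in 1 of the 4 cell types. The SE, like that for moDC below, treats the genes of a list as independent and holds no spread between libraries. The gap in cDC1 thus goes against the explanation without excluding it, and the other gaps leave it open. The gaps address only other cells in the NOD sorts. Among marker lists past camera's test, red pulp macrophage (median -2.52) and monocyte and macrophage markers (-1.39) were lower in NOD pDC. Neutrophil markers were lower in NOD monocytes (-6.03), while erythroid markers were higher in NOD in both (3.72 and 2.49). Whether other cells in the B6g7 sorts raised the list there was not tested and stays open. In moDC the fall needs at least 34.01% of cDC1 RNA (22.95% at the median plus 2 SE) if cDC1 among the sorted cells are its whole cause. The 13 cDC1 markers reached a median of at most 15.8% of their NOD cDC1 level in any NOD library. This goes against cDC1 as the whole cause without excluding them, since that SE leaves out the correlation between genes. A part of the fall, and other cell types, stay open. Strain variants that lower mapping to the reference would act alike in all cell types, and equal effects on the whole list were not excluded (permutation p = 0.2765). Equal effects on every member were excluded: 34 of the 55 passed a cutoff that at most 21 passed with the residuals of the libraries permuted together (permutation p = 1.0e-04). By the F test 54.55% of the members differed between cell types, against 24.33% of all genes. This excludes only mapping as the sole cause in all members. A mapping loss beside changes that depend on the cell type stays open for every member.

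The second pattern is the share of chromosome 17 genes among those whose strain effect differs between the Rag-sufficient and Rag1-/- sets. Of 95 pairs of gene and cell type (42 genes), 74 or 77.9% differed more between B6g7 and B6 Rag1-/- than between NOD and NOD Rag1-/-. A different MHC haplotype in the B6 Rag1-/- mice could give this, with a bound of 75 set for it after the pattern had been seen. The pairs were chosen for an unequal strain effect and repeat genes over cell types, so this share cannot decide it and the haplotype stays open. A run effect equal in both strains cancels from these differences, and the sequencing run stays open beyond that: the median absolute difference was 0.600 in NOD and 2.38 in B6 (ratio 0.253), but the pairs were chosen for an unequal strain effect, so this ratio tests nothing. Reads shared between MHC class I copies would stay within that family. Outside it, 4 genes (D17H6S56E-5, Rgl2, Rps18 and Vars) were past the test in at least 2 cell types, or 8 with predicted names, which were set aside after the names had been seen. This goes against shared reads as the sole cause of the pattern, by a bound set after it had been seen. For the H2 genes themselves shared reads stay open. Whether expression or the mapping of alleles to the reference differs stays open, and the labels give no haplotype for B6 Rag1-/-.

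The third pattern is the higher level of B cell, T cell, neutrophil and erythroid markers in NOD cDC1, cDC2 and moDC. If B cells or their RNA in the sorts gave it, the B cell markers would be lower in Rag1-/- cells, as they were in every NOD Rag1-/- library of the 3 cell types, and would not be higher in NOD there: in cDC1 and moDC the Rag1-/- strains overlapped (largest gap -0.7105), but in cDC2 NOD Rag1-/- scored 0.883 to 1.19 and B6 Rag1-/- 0.0440 to 0.472 (gap 0.4105; list median 0.99, camera adjusted p = 0.40), which leaves it open in cDC2. The NOD Rag1-/- libraries also came from another run, other sort dates and more sorted cells than the NOD libraries. Their lower scores thus cannot tell missing B cells from these differences. Fewer sorted cells do not account for the strain difference among libraries of 2000 cells, where the lowest NOD score was above the highest B6g7 score by 2.90 in cDC1 and 2.077 in cDC2, but among cDC2 libraries of 5000 cells the scores overlapped (gap -0.1512), which leaves it open there. All cDC1 and cDC2 libraries of 2000 cells were sorted on 10.26.2015, and on 01.05.2016 the cDC1 scores overlapped (0.339 to 1.95 in NOD, -0.277 to 0.726 in B6g7), with fewer cells in NOD. In Rag-sufficient pDC, all of 2000 cells and sorted on 10.16.2015, the B cell score was lower in NOD (-0.151 to 0.736) than in B6g7 (0.768 to 2.16). B cells in the sorts do not explain the erythroid markers, which were also higher in NOD Rag1-/-, and whether whole cells, fragments or free RNA carried them was not tested.

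The counts of genes were set against other groupings of the same libraries, in which 1 grouping is the real one. Chance can be excluded for cDC1 (2738; highest other 858; 1 of 100 as large), cDC2 (2947; 936; 1 of 100), moDC (4071; 3309; 1 of 100) and the genes shared by 5 cell types (322; 0; 1 of 100). The F test gave 3264 genes (417; 1 of 100). For the difference between the sets, cDC2 gave 154 (307; 4 of 100, and 532; 3 of 400, and with the date pairs of the Rag1-/- libraries kept 773; 12 of 400). In pDC it was 187 (5169; 53 of 100). In cDC1 it was 29 (162; 3 of 100), and with the date pairs kept the share (341; 18 of 400) was near 1 in 20. Permuting the strains also removes a strain effect that is equal in all cell types or in both sets. These groupings thus cannot tell unequal strain effects from equal ones. Chance is not taken as excluded for the F test or for the difference between the sets. Groupings with several times the real difference, as in cDC1, cDC2 and pDC, may hold the strain effect itself or other structure among the libraries. For 3 against 3 libraries 10 splits are too few for a share under 0.05: pDC 1684 (highest other 22), monocytes 2057 (38), Rag1-/- cDC1 219 (0), Rag1-/- cDC2 307 (0), each the largest of its 10. In Rag1-/- pDC 4 of 10 splits gave as many genes as the real 602, and the highest, 5331, set B6 Rag1-/- 1 and 2 with NOD Rag1-/- 3 against the rest. The Rag1-/- moDC, with 2 B6 libraries, were not split.

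Strain effects that differed between groups were the 3264 genes of the F test across the 5 cell types and, between the Rag-sufficient and Rag1-/- sets, 29 genes in cDC1, 154 in cDC2, 81 in moDC and 187 in pDC. Among gene groups, camera's test with the preset correlation passed in cDC1 for type I genes (median difference -0.44), MHC class I (-0.00732, with the test's direction upward), MHC class II (0.33) and cholesterol synthesis (-0.47). In cDC2 it passed for MHC class I (0.11), costimulation (-0.61) and cell cycle (-0.79). In moDC it passed for interferon-gamma-associated (0.49), interferon production (0.13), MHC class I (-0.0208, direction upward), MHC class II (0.46), cholesterol synthesis (0.39), cell cycle (-0.94), immediate early (0.30) and diabetes-locus genes (0.34). In pDC it passed for MHC class I (0.55), cell cycle (-1.90) and immediate early genes (0.47). None of these gene groups passed with an estimated correlation. With each library left out in turn, the calls that held were type I and MHC class I in cDC1, MHC class I in cDC2 and pDC, and MHC class II in moDC. The cell cycle difference was -0.16 in cDC2 and -0.17 in pDC without NOD Rag1-/- 2, and -0.43 in moDC without B6 Rag1-/- 2 (camera adjusted p = 0.21, 0.215 and 0.14). Of the 12 marker lists 9, 10, 5 and 2 also passed in cDC1, cDC2, moDC and pDC, and they were set aside after this had been seen. With an estimated correlation 4, 2, 4 and 0 did, among them B cell and T cell markers in cDC1 and moDC and NK cell and monocyte and macrophage markers in cDC2. Whether fewer macrophages among NOD pDC account for the lower gene groups there was not tested.

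A library far from the others of its group was found in 8 of 144 tests over 24 measures in the 6 groups of 5 or 6 libraries, where chance gives about 1 in 20, or 7.2. For the type I score cDC1 B6g7 1 was at 5.05 (nearest other 4.69), for the interferon-gamma-associated score moDC B6g7 1 at 5.17 (4.87) and for cholesterol synthesis cDC2 B6g7 5 at 3.98 (4.23). cDC1 B6g7 2 was at 8.89 for cDC1 markers (8.96) and at 3.70 for pDC markers (3.07). For platelet markers cDC1 NOD 2 was at 3.62 (0.781) and moDC NOD 3 at 0.216 (0.571). The total of cDC1 B6g7 6 was 19.74 M (16.83). Groups of 2 or 3 libraries were not examined in this way. In Rag1-/- pDC the TMM factor of B6 Rag1-/- 3 was 1.14, against 0.587 and 0.612 in the other B6 libraries.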

How the results depend on the processing

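Added after the data were seen were DESeq2, its size factors in edgeR, transcripts as deposited, limma with a pseudocount of 1 CPM, the estimated correlation, leaving out NOD libraries by B cell score, leaving out libraries from the comparison of the strain effects, the F test, the shared genes the score between genotypes and the lists, and no scaling of that score. The cause of the differences below was not tested, except that fewer libraries give less power. The type I medians of the 5 Rag-sufficient contrasts kept their sign under every alternative. DESeq2 size factors, no filter on low counts, transcripts as deposited, libraries of low RNA integrity left out and an additive sort date left every count within 1.5 times. Among the named genes, alternatives other than leaving out a library gave 5847 results on the same side of the threshold, 642 weaker, 5 stronger and 2 reversed, and leaving out a library 3783, 364, 9 and none. The reversed genes were both in cDC2: Tap1 was at 0.11 with the libraries of 10.26.2015 only, and Hspa8 at 0.30 with those of 01.05.2016 only.

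Without a sort date term the counts were 1141 in cDC1, 1291 in cDC2, 1637 in moDC, 597 in pDC and 617 in monocytes, and 17, 65, 30 and 95 for the difference between the sets in cDC1, cDC2, moDC and pDC. With libraries of 10.26.2015 only they were 1513 in cDC1 and 1682 in cDC2. Without the NOD libraries of the highest B cell scores they were 1424 and 1903. In fits per cell type moDC had 2690 genes, Rag1-/- cDC1 510, cDC2 565 and pDC 85, and 13 were shared by 9 contrasts. DESeq2 gave 491, 703, 500 and 1675 in Rag1-/- cDC1, cDC2, moDC and pDC. In Rag1-/- cDC2 and moDC limma gave 499 and 320 with a pseudocount of 0.25 CPM, 590 and 331 with 1 CPM, and 601 and 317 with 4 CPM. For the difference between the sets in cDC1, cDC2 and moDC it gave 44, 299 and 181 with 1 CPM and 50, 382 and 239 with 4 CPM, where the type I difference in pDC passed camera's test at 0.21. The authors' post-processed values gave 308 in Rag1-/- moDC. With an estimated correlation 7 gene group tests passed in place of 37, and the type I list no longer did in cDC1 (-0.55), moDC (-0.60), pDC (-0.43), Rag1-/- cDC2 (-0.73), moDC (-0.55) and pDC (-0.76), nor its difference between the sets in cDC1 (-0.44). Without scaling the B6 moDC score difference between genotypes passed at 1.10.

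With replicate numbers as a block the counts were 1085 in pDC, 1227 in monocytes, and 88, 115, 38 and 114 in Rag1-/- cDC1, cDC2, moDC and pDC. Only in Rag1-/- cDC1 does each number stand for 1 sort date that pairs the strains, and there, among the named genes, gene groups and marker lists, the block ended the calls of 7 genes and brought the cDC2 markers past camera's test, all given with that contrast, and changed no other. The lists other than the type I list were read with it only after the data were seen. Elsewhere the numbers do not pair the strains in this way, although many libraries of 1 number share a sort date, and in Rag1-/- cDC2, moDC and pDC libraries of other numbers share one across the strains. Every NOD library correlated best with its own number in none of the other contrasts, and in Rag1-/- pDC same-numbered libraries correlated at -0.66 to -0.11.

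Leaving out 1 library ended 15 of the 37 gene group calls. Leaving out 1 library at a time gave 118 to 159 genes in Rag1-/- cDC1, 179 to 325 in cDC2, 81 to 147 in moDC and 246 to 3183 in pDC, the highest without B6 Rag1-/- 3. Where a B6 moDC library was left out, the lone one was assumed to vary like the other groups. The difference between the sets ranged from 49 to 350 genes in cDC2 and from 88 to 2868 in pDC. The type I median in Rag1-/- moDC ranged from -0.997 to 0.10, the latter without B6 Rag1-/- 2. Its difference between the sets ranged from -0.33 to -0.10 in cDC2 (past camera's threshold without B6 Rag1-/- 3, -0.28, or NOD Rag1-/- 2, -0.33), from -0.69 to 0.44 in moDC (-0.69 without B6 Rag1-/- 2, -0.03 without NOD 2, 0.44 without B6 Rag1-/- 1) and from 0.0234 to 0.45 in pDC (past it without B6 Rag1-/- 1, 0.45, or NOD 3, 0.33). The B6 moDC score difference between genotypes ranged from 0.22 to 1.47 and passed without B6g7 1, at 0.91. With about 16.3 M counts per library, depth limits genes of few CPM, such as Rag1.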

Other observations

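The levels below were chosen after they had been seen, as were the markers named, and no further test was run on them.

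The monocyte surface marker Ly6c2 was at 1988 ± 182 CPM in B6g7 and 282 ± 3.88 in NOD monocytes. In pDC it was at 8561 ± 179.6 and 1325 ± 140.1 CPM, and at 13160.0 ± 9871 and 646 ± 539 in the Rag1-/- mice. Its relative Ly6c1 was higher in NOD in every Rag-sufficient contrast, and whether reads were assigned between these genes was not tested. Clec9a, a receptor for dead cells, was at 508 ± 44.3 CPM in B6g7 and 361 ± 44.8 in NOD cDC1, and at 161 ± 7.71 and 91.2 ± 0.901 in pDC. The calprotectin gene S100a8 was at 1036 ± 742 CPM in B6g7 and 15.8 ± 2.04 in NOD monocytes, and at 52 ± 61.9 and 1507 ± 1247 CPM in moDC of B6 Rag1-/- (n = 2) and NOD Rag1-/- mice.

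Siglech, a pDC receptor, was between 4661 and 7707 CPM in the 4 pDC groups, at 18.1 ± 14.2 in NOD moDC and at 1.22 ± 1.17 in B6g7 moDC. Xcr1, which marks cDC1, was between 899 and 1575 CPM in the 4 cDC1 groups, at 50 ± 10.1 in NOD moDC and at 15.5 ± 1.11 in NOD Rag1-/- moDC. The adhesion gene Vcam1, high in red pulp macrophages, was at 2070.0 ± 1857 CPM in B6 Rag1-/- and 424 ± 324 in NOD Rag1-/- cDC2, against 89 ± 39.2 in B6g7 and 56.5 ± 19.6 in NOD cDC2. Hbb-bs was at 1894 ± 246 CPM in NOD Rag1-/- and 378 ± 324 in B6 Rag1-/- cDC1.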
